A study of Homo sapiens with 18 samples.

How the data were processed

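Total RNA of 6 human pancreatic cancer cell lines was measured on Illumina Human HT-12 v4 BeadChips, on which each transcript is read by an oligonucleotide probe carried by many beads. Per the labels, MiaPaCa2, Panc1 and SU8686 were resistant to dasatinib, an inhibitor of SRC family, ABL and other kinases, and Panc0403, Panc0504 and Panc1005 were sensitive to it. Each line had 3 arrays, numbered replicates 1 to 3 and described as biological triplicates, which made 18 arrays, with 9 arrays per response. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase I on RNeasy columns, checked on a Bioanalyser, and turned into biotinylated cRNA with an Ambion MessageAmp kit. The labels name no drug treatment of the cells before extraction.

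The array codes in the labels placed the 18 arrays on 3 slides of 6 arrays each. Slide 1 held Panc0403 and Panc0504, slide 2 held Panc1005 and SU8686, and slide 3 held MiaPaCa2 and Panc1. Slides 1 and 3 therefore each held a single response, and slide 2 alone held a line of each.

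The deposited intensity table gave, per the file headers, the bead intensity and the detection p-value of 48107 probes on each array. Neither background subtraction nor normalization was visible in these intensity values: the median intensity per array ran from 110.4 to 135.2 on a linear scale. The image software, its version and the processing steps are not given in the sources used here. The authors' series matrix held log2 values of 47323 of these probes. Its scale and centring were settled from the values: each column ranked its probes as the array's intensities did, and 4 sets of arrays shared identical value distributions. These sets were slide 1, slide 2, 5 arrays of slide 3, and the remaining array of slide 3, replicate 3 of Panc1. The column medians ran from 6.87 to 7.04 on the log2 scale. Because these log2 values were quantile normalized by the authors in 4 separate sets, levels across slides are not on 1 scale there, and the series matrix served only as an alternative. It had 13 missing values.

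Background was corrected by normexp with the negative control distribution inferred from the detection p-values, with an offset of 16, followed by quantile normalization of the 18 arrays and log2 (neqc in limma 3.58.1, R 4.3.3). The 784 probes found only in the intensity table had a mean detection p of 0.492 and entered the normalization but no test. Gene symbols came from the platform annotation, which named 1 symbol for 30113 probes, several for 8 and none for 17202. Of the annotated probes, 30074 matched a current gene record by Entrez identifier, which changed 0 symbols, and 47 kept the symbol of the annotation. Probes with several symbols or none were left out, as were 143 probes of XIST or the Y chromosome. A probe counted as detected at a detection p under 0.01, and 15402 named probes were detected on at least 3 of the 18 arrays. Each gene was represented by its detected probe of highest mean, which left 11597 genes, 3012 of them with more than 1 detected probe. Among 113 genes singled out by the rule below or after the data were examined, 31 had more than 1 detected probe, and in 0 did the probes go opposite ways by over 0.5. Probes of a gene could differ in size. TGFBR2 was at -3.41 for the probe used and -3.07 and -0.327 for its others. DDR1 was at -1.03 and -0.19, whereas VIM was at 5.19 and 6.02. All differences are of normalized log2 intensity, resistant minus sensitive. With the offset, differences of dim genes are understated.

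Response is a property of a line, so the line was the replicate in the first comparison: the 3 arrays of a line were averaged, and limma's moderated test compared 3 resistant with 3 sensitive line means, with Benjamini-Hochberg adjustment over 11597 genes at 0.05. The second comparison fitted a mean per line to the 18 arrays and counted genes for which all 9 contrasts of a resistant with a sensitive line had the same sign, an adjusted p under 0.05 and a log2 difference of at least 1. The same fit gave the genes that differed in each of the 15 line pairs, and the genes of a line that differed from each of the other 5 lines in 1 direction. For gene groups, 30 lists were drawn up before the data were examined, covering dasatinib targets, epithelial and mesenchymal states, pancreatic cancer subtypes, signalling outputs, metabolism, stress, and markers of other cell types. The 28 lists with at least 5 measured members were tested with limma's camera on the line means, with a preset correlation between genes of 0.01. Camera with an estimated correlation and limma's fry were run as alternatives. Two-sided exact enumeration of the 10 splits of the lines compared pair counts.

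The rule for naming genes was also set before the data were examined. It took genes past the threshold of the first comparison or, failing these, of the second, up to 3 higher and 2 lower genes specific to each line, the 2 members of largest difference in each list, and 23 genes by name. Of these 23, ABL2, ZEB1 and GATA6 were not detected. Genes outside the rule are said to have been chosen after their values were seen. Where a gene was detected on none of the arrays of a group, a fold is given as a lower bound. It sets the mean of the other group against, on each undetected array, the lowest normalized signal among detected probes or the gene's own signal, whichever was higher.

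The code was tested on simulated arrays with the means of the 11597 genes and known changes, after a first run on the real arrays had supplied those means. With the between-line variance of each gene in the real arrays, the first comparison recovered 1.23% of genes changed by 1 on the log2 scale, 45.5% of those changed by 2 and 82.8% of those changed by 4. With 0.1 times that variance the shares were 34.6%, 81.8% and 96.9%. Lines were drawn independently in the simulation, whereas real lines that shared a slide were nearly alike, so these shares may not hold for the real arrays. The test over all 9 line pairs recovered 0%, 60% and 85.9%. The test for line-specific genes recovered 3.33%, 56.9% and 88.2%. Both were simulated with no between-line variance apart from the set changes, so these shares may be too high for the real lines. In the simulation of gene lists, 3 of 3 lowered lists were called and 1 list that had not been changed was called as well. Its genes were drawn independently, whereas the estimated correlation between members was 0.892 in the real epithelial list. It therefore does not measure false calls for lists whose members move together.

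Alternatives tried were no background correction, an offset of 50, median centring, the authors' log2 values, no filter and a stricter filter on detection, all probes as features, each replicate number or each line left out, slide or replicate number as a block, slide 2 alone, the line as a random block, and other settings of limma. The comparison of slides 1 and 3 alone, and the counts of genes whose arrays do not overlap, were added after the data were examined. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value. Apart from the words biological triplicates, the labels say nothing of how replicates were grown, so p-values from arrays of a line measure the spread between those arrays.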

Results

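The transcriptomes of 3 pancreatic cancer lines resistant to dasatinib (MiaPaCa2, Panc1 and SU8686) and 3 sensitive lines (Panc0403, Panc0504 and Panc1005) were profiled on 3 arrays per line. Between 31% and 35% of probes were detected per array, and 11597 genes were tested. The design asks which genes distinguish resistant from sensitive lines. All 6 are established lines of pancreatic cancer, most often a ductal adenocarcinoma (PDAC).

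Replicate 2 of every labelled line differed from replicates 1 and 3 in genes that are usually switched on or off as a stable property of a cell line. CDKN2A, the cell cycle inhibitor often deleted in pancreatic cancer, was bright on replicates 1 and 3 of the arrays labelled Panc0403 (mean 10.37 on the log2 scale), Panc0504 (10.74), Panc1005 (9.77) and SU8686 (10.08). It was not detected on replicate 2 of any of these, a difference of at least 20.4-fold, 24.3-fold, 13.8-fold and 16.9-fold. SMAD4, a transducer of TGF-beta signals, was not detected on replicate 2 of Panc0403 and Panc0504, at least 9.42-fold and 9.96-fold below replicates 1 and 3. MTAP, the neighbour of CDKN2A on chromosome 9, was likewise undetected on replicate 2 of Panc1005 and SU8686, at least 14.1-fold and 10.6-fold lower. In the other direction, CDH2 (N-cadherin) was detected on replicate 2 alone in all 6 lines, at least 3.76-fold to 33.8-fold above the other replicates. CDH1 (E-cadherin) was detected in MiaPaCa2 and Panc1 on replicate 2 alone, at least 9.15-fold and 7.27-fold higher, as was the adhesion molecule EPCAM, at least 8.47-fold and 8.1-fold higher. CDH2 was singled out after its values were seen.

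Across all 11597 genes, replicates 1 and 3 of a line correlated at r = 0.994 to 0.996, while replicate 2 correlated with them at only 0.851 to 0.897. The nearest array of each of the 6 replicate 2 arrays carried the name of the other line on its slide, with r = 0.915 on slide 2 and 0.99 to 0.991 on slides 1 and 3. Replicates 1 and 3 of differently named lines on a slide correlated at 0.964 to 0.983, and lines on different slides at 0.725 to 0.89. These correlations are across genes, which are not independent replicates. From 179 to 304 genes per line were on in replicates 1 and 3 and off in replicate 2 or the reverse (detected against not detected, apart by at least 3 on the log2 scale), against 0 between replicates 1 and 3. Each line named below therefore stands for the arrays labelled with that name, and a mean ± SD over 3 lines rests on those labels. The lines of slide 1 were both sensitive and those of slide 3 both resistant, so an exchange of names within either slide leaves the response label as it is. On slide 2 it does not.

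**Figure D1:**
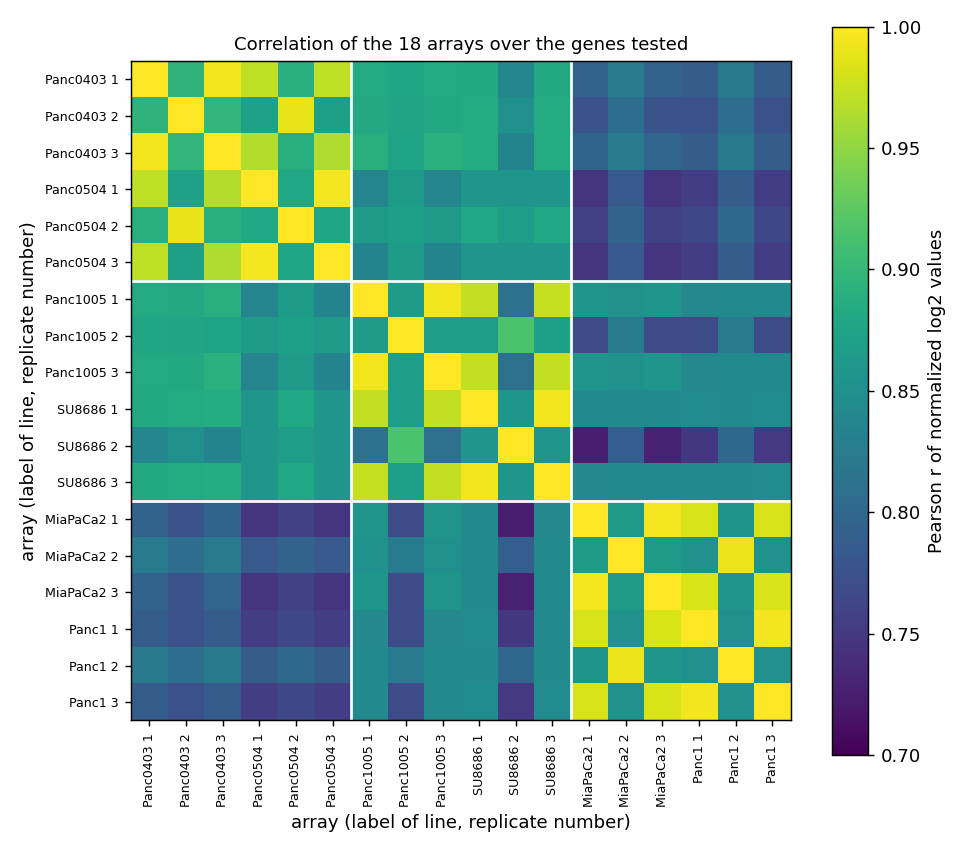
Pearson correlation of normalized log2 values over 11597 genes between each pair of the 18 arrays, ordered by slide (white lines) and labelled line, with the colour scale from 0.7 to 1. Replicate 2 of each line is closest to replicate 2 of the other line on its slide (r = 0.915 to 0.991), and replicates 1 and 3 of both lines on a slide form a block at 0.964 or above.

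KLHDC8B, a kelch-domain protein, was the gene that most clearly separated the responses. It averaged 8.33 ± 0.37 in resistant lines and 5.30 ± 0.37 in sensitive lines (SD, n = 3 lines each), was detected on all 9 resistant arrays and on 0 of 9 sensitive arrays, and was at least 4.7-fold higher in resistant lines. ID3, an inhibitor of basic helix-loop-helix transcription factors, averaged 12.04 ± 0.42 against 9.13 ± 0.28, and the receptor FGFR3 averaged 9.44 ± 0.19 against 7.09 ± 0.42. Lower values in resistant lines were seen for MYEOV (6.38 ± 0.91 against 10.56 ± 0.21), for the platelet receptor PEAR1 (5.38 ± 0.03 against 7.46 ± 0.19) and for the inhibin subunit INHBE (at least 2.27-fold). All of these except KLHDC8B were chosen after their values were seen, as the genes of smallest p. Part of this separation rested on replicate 2. ID3 was not detected on replicate 2 of the 3 sensitive lines but averaged 10.87 to 11.20 on their replicates 1 and 3, and without replicate 2 its difference was 1.49 in place of 2.91. Without replicate 2, FGFR3 was lower in SU8686 (8.05) than in Panc0403 (8.29) or Panc0504 (8.78), and INHBE was at 5.78 in Panc1005, below the 5.80 to 5.96 of the resistant lines. KLHDC8B, PEAR1 and MYEOV differed by 3.39, -2.39 and -5.23 without replicate 2, although MYEOV was detected in MiaPaCa2 and Panc1 on replicate 2 alone. The small SD of PEAR1 in resistant lines also rested on replicate 2. Its means in MiaPaCa2, Panc1 and SU8686 were 5.38, 5.35 and 5.42 with all arrays, but 4.715, 4.756 and 5.71 without replicate 2.

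With the line as the replicate, limma called 0 of 11597 genes, and the lowest adjusted p was 0.134, shared by KLHDC8B, ID3 and PEAR1. At an unadjusted p under 0.05 there were 2190 genes, 1207 higher and 983 lower in resistant lines, where chance gives 580 if the 6 lines are independent. The 3 line means of each response did not overlap for 1397 genes that were higher and 1124 that were lower, or 21.7% of genes, where chance gives 10% on the same assumption. Lines that shared a slide were nearly alike, so that assumption was not met and both chance values may be too low for these arrays. The count of genes called was 365 without Panc1005 and 2333 without SU8686, the lines of slide 2, and 2 without replicate 3 (ID3 and MYEOV). It was 3 with slide as a block (S100A8, VTCN1 and ALDH3B2, all higher in SU8686), 3 within slide 2 alone (CD14, DEFB1 and NFE2, all higher in SU8686), and 758 when arrays entered singly with the line as a random block. The fits with slide as a block and within slide 2 set 1 line against 1 line, SU8686 against Panc1005. Their spread comes from line pairs on slides 1 and 3 that differed in 0 and 1 genes, or from arrays of a line, so their p-values do not test response.

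Among the kinases that dasatinib binds, none passed the test. SRC itself averaged 9.89 ± 0.30 in resistant and 10.37 ± 0.45 in sensitive lines (limma adjusted p = 0.395), and ABL1 averaged 9.56 ± 0.60 against 8.91 ± 0.09 (adjusted p = 0.309). YES1 averaged 8.71 ± 0.59 against 8.17 ± 0.28 (adjusted p = 0.402). FYN averaged 6.03 ± 1.07 against 8.26 ± 0.40 and was detected on 3 of 9 resistant and 9 of 9 sensitive arrays, whereas LYN averaged 11.42 ± 0.20 against 10.29 ± 0.64 (adjusted p = 0.239 for both). EPHA2 averaged 8.81 ± 0.58 against 9.98 ± 0.52 (adjusted p = 0.244) and DDR1 9.67 ± 1.76 against 10.70 ± 0.26 (adjusted p = 0.498). The largest differences in the list of other dasatinib-binding kinases were those of EPHA1 (-2.83 ± 0.86, SE, n = 3 lines each), detected on 4 of 9 resistant and 9 of 9 sensitive arrays, and PTK6 (-2.31 ± 0.69), with adjusted p = 0.239 for both. Caveolins CAV1 and CAV2, which belonged with EPHA2 to an expression signature of dasatinib sensitivity in breast cancer lines, differed by -1.01 ± 0.39 and -0.76 ± 0.29 (SE, n = 3 lines each), with adjusted p = 0.251 and 0.252. Of the 6 markers in that list, 3 had higher and 3 lower means in resistant lines. The largest difference was that of IGFBP2, which was higher by 1.27 ± 0.33 (adjusted p = 0.239) and detected on 5 of 9 resistant and 1 of 9 sensitive arrays. Among growth factor receptors, EGFR differed by -0.40 ± 0.21, MET by -1.34 ± 0.36, AXL by -1.22 ± 0.24 and ERBB3 by -2.28 ± 1.37, with adjusted p = 0.327, 0.239, 0.237 and 0.382.

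Of the tumour suppressors fixed by name, CDKN2A differed by -2.52 ± 0.97 between resistant and sensitive lines and MTAP by -3.04 ± 0.83, while SMAD4 differed by 1.93 ± 0.57 (SE, n = 3 lines each; limma adjusted p = 0.252, 0.239 and 0.239). TGFBR2, the type II receptor for TGF-beta, differed by -3.41 ± 1.06 (adjusted p = 0.24). CDKN2A and MTAP were detected on 0 of 3 arrays of both MiaPaCa2 and Panc1. None of these passed the threshold, and all 4 differed between replicate 2 and the other replicates of at least 2 lines.

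Every resistant line differed from every sensitive line in 2 genes at an adjusted p under 0.05 and a log2 difference of at least 1 (limma, 18 arrays). KLHDC8B was higher, by at least 2.22 in each of the 9 line pairs, with line means of 7.91 in SU8686, 8.47 in MiaPaCa2 and 8.60 in Panc1 against 4.96 to 5.69 in the sensitive lines. LETM2, a homologue of a mitochondrial ion exchanger, was lower: it averaged 5.46 ± 0.23 in resistant and 7.41 ± 0.43 in sensitive lines (SD, n = 3 lines each), was detected on 0 of 9 resistant and 9 of 9 sensitive arrays, and was at least 2.56-fold lower in resistant lines. As the call required, the 2 genes separated SU8686 from Panc1005 on slide 2, by 2.22 and -1.87, and slide 3 from slide 1, by 3.43 and -2.0. KLHDC8B was the only gene whose 9 resistant and 9 sensitive arrays were apart by at least 1, a count added after the data were examined.

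Without replicate 2 the count over 9 line pairs was 44, with 34 higher and 10 lower, and without replicate 1 or replicate 3 it was 0. LETM2 was not among the 44. Genes called without replicate 2, chosen after their values were seen, included SNAP25, a synaptic vesicle fusion protein (smallest difference 1.82), GPR162 (1.86) and the metallothionein MT1M (1.8) among the higher. MYEOV (-1.75) and the peptide hormone EDN1 (-1.43) were among the lower. The count was 0 with no background correction and 0 on the authors' log2 values, and 1 with an offset of 50. With a replicate block it was 9, with 3 higher and 6 lower.

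**Figure D2:**
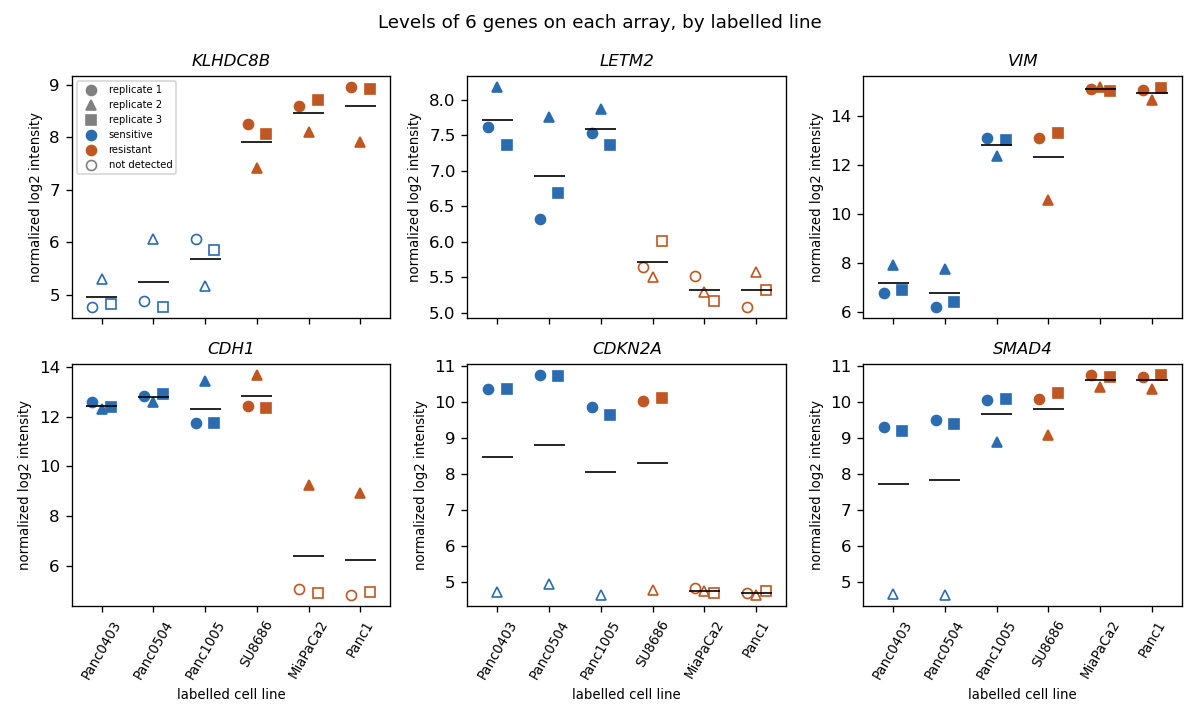
Normalized log2 intensity of 6 genes on each of the 18 arrays, by labelled line, with replicate number as symbol shape, response as colour, open symbols for arrays where the gene was not detected, and a bar at the mean of each line. KLHDC8B and LETM2 separate the 9 resistant from the 9 sensitive arrays, while CDKN2A, SMAD4 and CDH1 differ between replicate 2 and replicates 1 and 3 of several lines.

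Epithelial genes were lower in the resistant lines as a group. All 35 measured members of the list of epithelial junction and keratin genes had lower means in resistant lines, with a median difference of -2.08 (camera adjusted p = 1.74e-11; adjusted p = 0.453 with an estimated correlation). KRT7, a ductal keratin, averaged 7.67 ± 3.96 in resistant and 12.81 ± 0.42 in sensitive lines, and EPCAM averaged 8.96 ± 4.31 against 13.87 ± 0.14 (SD, n = 3 lines each). CDH1 averaged 6.40 in MiaPaCa2 and 6.24 in Panc1, but 12.82 in SU8686, above the 12.30 of Panc1005. The list's shift lay between slides 3 and 1, with a median of -3.39. Within slide 2, which alone held a line of each response, the median was 0.19, the opposite way. This list was 1 of 12 of the 28 lists that camera called, 11 lower and 1 higher in resistant lines, and 0 of the 12 calls held with an estimated correlation. Vimentin (VIM), a mesenchymal filament protein, averaged 15.09 in MiaPaCa2 and 14.92 in Panc1, 12.31 in SU8686 and 12.81 in Panc1005, and 7.17 and 6.77 in Panc0403 and Panc0504. The mesenchymal list as a whole did not pass (13 members higher and 10 lower, median difference 0.26, adjusted p = 0.592), but without replicate 2 it was called higher (adjusted p = 0.0207).

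The classical PDAC, basal-like PDAC and secretory lists also fell in the resistant lines. Of 26 measured classical PDAC genes 25 had lower means, with a median of -1.85 (camera adjusted p = 1.54e-07; adjusted p = 0.453 with an estimated correlation). S100P, a calcium-binding protein abundant in pancreatic cancer, averaged 5.87 ± 1.20 against 11.98 ± 5.02, and the glutathione peroxidase GPX2 averaged 5.32 ± 0.44 against 10.44 ± 4.52 (SD, n = 3 lines each). Of 16 basal-like PDAC genes 14 had lower means, median -1.90 (adjusted p = 2.33e-04; adjusted p = 0.433 with an estimated correlation), among them the protease inhibitor CST6 (-4.56 ± 2.29, SE) and FGFBP1 (-3.94 ± 0.98). Of 16 mucin and secretory genes 13 had lower means, median -1.83 (adjusted p = 0.00402; adjusted p = 0.529 with an estimated correlation). Among these, mesothelin (MSLN) differed by -5.08 ± 1.54 and lipocalin 2 (LCN2) by -4.83 ± 2.15. Between SU8686 and Panc1005, 1 line each, the medians of the classical PDAC, basal-like and mucin lists were 0.47, -0.02 and 0.76, so the shift of these lists lay between slides 3 and 1.

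Lists of growth signalling were lower in resistant lines. MAPK output genes had 14 of 21 members lower, median -0.87 (camera adjusted p = 0.00676; adjusted p = 0.31 with an estimated correlation), with the ERK phosphatases DUSP5 and DUSP4 at -2.94 ± 0.72 and -2.87 ± 0.86 (SE, n = 3 lines each). Targets of the YAP and TEAD transcription regulators had 16 of 24 lower, median -0.51 (adjusted p = 0.00676; adjusted p = 0.31 with an estimated correlation). Among them tissue factor (F3) differed by -4.28 ± 1.20, and DLC1 was at least 5.43-fold lower. Receptor tyrosine kinases and ligands had 16 of 23 lower, median -0.40 (adjusted p = 0.00681; adjusted p = 0.31 with an estimated correlation), with the EGFR ligands TGFA and HBEGF at -3.86 ± 1.12 and -2.77 ± 0.36. Between SU8686 and Panc1005, 1 line each, the medians of these 3 lists were -0.50, -0.37 and -0.39. They were -0.155, -0.408 and -0.168 in replicates 1 and 3, but -0.926, -0.654 and -0.531 in replicate 2, 1 array per line. The YAP and TEAD list was not called without SU8686 (adjusted p = 0.0638) or on slides 1 and 3 alone (adjusted p = 0.0823).

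Stress and inflammatory lists were lower as well. The immediate early and stress list had 19 of 27 members lower, median -0.33 (camera adjusted p = 0.00681; adjusted p = 0.433 with an estimated correlation), with the stress pseudokinase TRIB3 averaging 9.85 ± 0.98 against 12.60 ± 0.19 and DDIT3 averaging 8.06 ± 0.91 against 10.36 ± 0.66 (SD, n = 3 lines each). NF-kB and cytokine genes had 20 of 25 lower, median -0.67 (adjusted p = 0.00402; adjusted p = 0.559 with an estimated correlation), including IL1A (-2.91 ± 1.99, SE) and the prostaglandin synthase PTGS2 (-2.63 ± 1.36); without replicate 2 this call was lost (adjusted p = 0.404). The NRF2 and detoxification list had 17 of 24 lower, median -0.60 (adjusted p = 0.0139; adjusted p = 0.529 with an estimated correlation), with ALDH3A1 at -4.70 ± 1.91 and AKR1C3 at -4.12 ± 1.60. It was not called without Panc0504 (adjusted p = 0.107) or without SU8686 (adjusted p = 0.0784). Focal adhesion genes and SRC substrates had 21 of 29 lower, median -0.20 (adjusted p = 0.0329; adjusted p = 0.453 with an estimated correlation), with the integrins ITGA2 and ITGB4 at -2.78 ± 0.88 and -2.41 ± 0.85. That call was lost without replicate 1 (adjusted p = 0.0845), without replicate 3 (adjusted p = 0.0631), without Panc0504 (adjusted p = 0.0919), without SU8686 (adjusted p = 0.0897), under the stricter detection filter (adjusted p = 0.132) and on slides 1 and 3 alone (adjusted p = 0.057). Between SU8686 and Panc1005 the medians of these 4 lists were 0.03, 0.22, 0.29 and -0.21. Between slides 3 and 1 they were -0.73, -1.19, -0.72 and -0.37. For the first 3 of these lists the shift thus lay between slides 3 and 1, where slide and response cannot be told apart.

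The neuroendocrine and neural list was the only one called higher in resistant lines, with 7 of 9 measured members higher and a median of 0.50 (camera adjusted p = 0.0139; adjusted p = 0.31 with an estimated correlation). The secretory granule protein SCG2 averaged 9.67 ± 3.38 against 5.49 ± 0.31 and SNAP25 averaged 8.62 ± 0.84 against 5.53 ± 0.47 (SD, n = 3 lines each). The median level of the list was 8.46 to 8.84 on replicates 1 and 3 of MiaPaCa2 and Panc1, but 6.27 and 5.96 on their replicate 2 and 6.02 to 6.17 on the arrays of SU8686, against 5.94 to 6.12 in the sensitive lines. SNAP25 was not detected on replicate 2 of MiaPaCa2 and Panc1, at least 30-fold and 31.3-fold below replicates 1 and 3. The call was lost without Panc1005 (adjusted p = 0.0524) and with no filter on detection (adjusted p = 0.135).

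The other lists did not pass camera in the main fit, although several did with some arrays left out, another filter or another setting. Cell cycle genes had 17 of 31 members higher (adjusted p = 0.777), with MCM2 at 1.13 ± 0.70 and TYMS at 1.12 ± 0.80 (SE, n = 3 lines each). They were called lower without Panc0504 (adjusted p = 0.0275) or MiaPaCa2 (adjusted p = 0.0107), and their median between SU8686 and Panc1005 was -0.78. Interferon response genes had 21 of 31 lower (adjusted p = 0.263), with IFI27 at -3.08 ± 1.91 and BST2 at -2.87 ± 1.26. They were called lower without SU8686 (adjusted p = 2.11e-05) and on slides 1 and 3 alone (adjusted p = 1.98e-04), whereas their median between SU8686 and Panc1005 was 1.00. Slide and response cannot be told apart on slides 1 and 3 alone, so the p-values there do not test response. Markers of stellate cells and fibroblasts had 6 of 9 members higher (median 1.44, adjusted p = 0.0751), with COL1A2 at 3.83 ± 0.90 and COL5A2 at 4.27 ± 1.09, and were called higher without replicate 2, MiaPaCa2 or Panc1 (adjusted p = 0.029, 0.0324 and 0.0283). Immune cell markers had 5 of 9 lower (adjusted p = 0.777), with LYZ at -1.78 ± 1.24 and CD14 at 1.12 ± 0.86. Adjusted p was 0.108 for ribosomal proteins, 0.0881 for PDAC driver and 9p21 genes, 0.125 for quasi-mesenchymal PDAC genes, 0.341 for acinar and islet genes, 0.548 for other dasatinib-binding kinases and 0.592 for the retinoid, WNT and NOTCH list. The ribosomal list was called in 5 other settings, among them without replicate 1 or 3 and with no filter (adjusted p = 0.0106, 0.00902 and 0.0243). The driver list was called without replicate 2 or on slides 1 and 3 alone (adjusted p = 0.0382 and 0.039). The quasi-mesenchymal list was called without replicate 1 or Panc1 (adjusted p = 0.0457 and 0.0451). Each was called lower in resistant lines. Adjusted p was also 0.592 for cancer-testis antigens, and was 0.691 for the breast cancer dasatinib markers, 0.777 for drug transport and for hypoxia, and 0.952 for cholesterol synthesis. The median difference and the direction of the test differed in sign for cancer-testis antigens, cell cycle and cholesterol synthesis, and the mean did so for cell cycle, drug transport, hypoxia and cholesterol synthesis. SRC family kinases and endothelial markers, with 4 measured members each, were not tested; their medians were 0.03 and 0.05. Over all genes tested, 0 members of any list passed; adjusted over the list alone, the largest counts were 10 of 23 receptor tyrosine kinases and ligands, 6 of 23 mesenchymal genes and 4 of 24 YAP and TEAD targets, and 0 of 35 in the epithelial list.

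**Figure D3:**
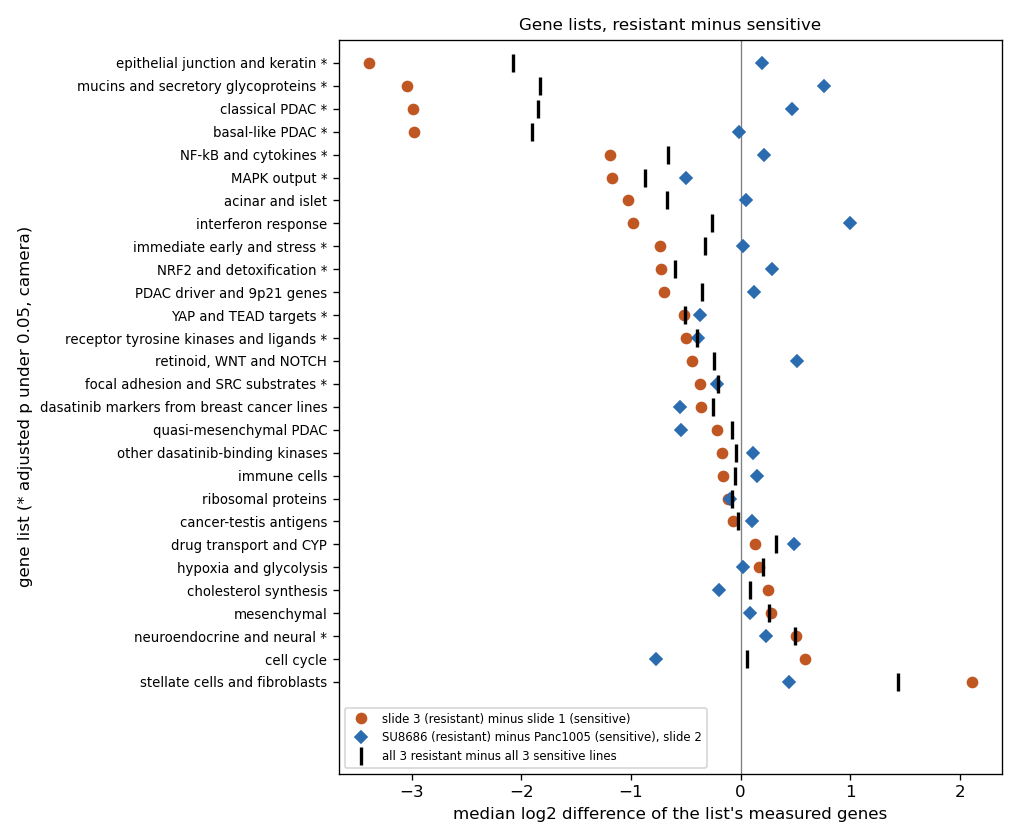
Median log2 difference, resistant minus sensitive, over the measured members of each of the 28 lists tested, for all 6 lines (bars), for slide 3 minus slide 1 (circles) and for SU8686 minus Panc1005 on slide 2 (diamonds), with lists called by camera marked by a star. The epithelial list lies at -3.39 between slides 3 and 1 and at 0.19 within slide 2.

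Pairs of lines were also compared within and across responses, as a measure of how far lines of 1 response differ among themselves. Among pairs of opposite response, MiaPaCa2 against Panc0504 had the most genes (2695 at an adjusted p under 0.05 and a log2 difference of at least 1), whereas SU8686 differed from its fellow resistant lines MiaPaCa2 and Panc1 in 1754 and 1387 genes. From the sensitive lines, SU8686 differed in 619 genes for Panc0403, 622 for Panc0504 and 57 for Panc1005. The median was 1430 genes over the 9 pairs of opposite response and 682 over the 6 pairs of the same response, a difference of 748 that the exact enumeration of 10 splits put at a two-sided p of 0.4, where 0.1 is the smallest p it allows. The 3 pairs that shared a slide had the fewest genes: 0 for MiaPaCa2 against Panc1, 1 for Panc0403 against Panc0504 and 57 for SU8686 against Panc1005. Without replicate 2, whose deviation lines on a slide shared and this fit counts as spread, these became 312, 860 and 562. The medians then became 3431 for opposite and 2844.5 for the same response. Without replicate 3 the medians were 180 and 17, and without replicate 1 they were 185 and 17.5.

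Slides 1 and 3, whose response labels do not depend on which line is which, gave the widest contrast. In 641 genes the 6 arrays of slide 3 and the 6 of slide 1 were apart by at least 1, with 220 higher and 421 lower on slide 3, the resistant side. The following genes were chosen after their values were seen, as those with the widest gaps. The adhesion molecule JAM3 (at least 32-fold), the homeobox factor PRRX2 (at least 23.3-fold), TM4SF18 (at least 70.8-fold) and the neuronal kinesin KIF1A (at least 11.6-fold) were higher on slide 3 and detected on 0 of 6 arrays of slide 1. The tropomyosin TPM2, detected on both slides, was higher by 4.81. The phosphatase regulator PHACTR3 (at least 81.8-fold), the basement membrane proteins LAD1 (at least 73.1-fold) and LAMB3 (at least 36.4-fold), and the serpin SERPINB5 (at least 50.8-fold) were lower and detected on 0 of 6 arrays of slide 3. SU8686 lay on the same side of Panc1005 for 141 of the 220 and 159 of the 421, and over all genes the differences on slide 2 and between slides 3 and 1 correlated at r = -0.105. As each of slides 1 and 3 held a single response, slide and response cannot be told apart in this contrast.

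With all arrays, SU8686 had the most genes that set it apart from all other lines: 20 higher and 1 lower. S100A8, a calcium-binding protein of inflamed epithelia, averaged 11.18 ± 0.72 in SU8686 and at most 6.03 elsewhere (SD, n = 3 arrays per line). The immune checkpoint ligand VTCN1 averaged 9.97 ± 1.70 against at most 5.45, and the aldehyde dehydrogenase ALDH3B2 averaged 8.61 ± 1.23 against at most 5.18, while the apoptosis inhibitor AVEN was lower (6.06 ± 0.59). Panc1005 had 3 such genes, TNFSF18 (8.40 ± 0.12), RIMS2 (6.95 ± 0.33) and the inflammasome sensor NLRP3 (7.5 ± 0.77), and Panc0504 had 1, the cystatin CST1 (11.88 ± 0.57 against 9.78 ± 0.19 in Panc0403). The call as specific to its line was kept in 10 of 10 other settings for S100A8, in 8 of 10 for VTCN1, ALDH3B2, TNFSF18 and CST1, in 6 of 10 for RIMS2, in 5 of 10 for NLRP3 and in 5 of 11 for AVEN. Panc0403, MiaPaCa2 and Panc1 had 0. Such a gene must differ from the other line on the slide, which 0 genes did on slide 3, 1 on slide 1 and 57 on slide 2. With all arrays, only a line of slide 2 could therefore have more than 1. The total of 25 became 762 without replicate 2 and 1 without replicate 1 or without replicate 3, and 8 under the stricter detection filter. Without replicate 2 the order of the lines turned: Panc0504 had the most, with 206 higher and 211 lower, against 117 and 4 in SU8686, 28 and 46 in Panc1005, 20 and 18 in Panc0403, 15 and 20 in MiaPaCa2, and 57 and 20 in Panc1. The median share of a gene's variance over the 18 arrays that lay between arrays of a line was 47.7%, against 30.8% between lines of 1 response and 13.6% between responses. Without replicate 2 these medians were 3.02%, 61.7% and 27.1%.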

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

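The tests of the replicate 2 arrays, of the likeness of lines on a slide and of the epithelial list were chosen after the results were seen, whereas the counts over other splits of the lines were planned.

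Replicate 2 of each line stood apart from replicates 1 and 3. Poor quality of those arrays was argued against by genes that replicate 2 gained. In every line at least 111 genes were detected on replicate 2 alone, with a normalized log2 signal higher by at least 3. CDH2 was among them in all 6 lines, although its lower bound in SU8686 was only 3.76-fold. A batch shared by all replicate 2 arrays was argued against by the difference of replicate 2 from replicates 1 and 3, which correlated over genes at most at r = 0.229 between lines on different slides. An exchange of replicate 2 arrays between the names of a slide, with replicates 1 and 3 rightly named, was argued against by their correlation with replicates 1 and 3 of the other line on the slide, at most 0.888 against at least 0.994 between replicates 1 and 3 of a line. The nearest array carried another line's name for 6 of the 6 replicate 2 arrays. Other ways of recording arrays under another line's name stay open, because that explanation was drawn from this value, which therefore does not test it. The labels give no difference between replicates, so no biological explanation was tested.

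Differently named lines on a slide were nearly alike in replicates 1 and 3. A slide effect that makes all its arrays alike was argued against, since replicate 2 correlated with replicates 1 and 3 of the other line at a median of only 0.862, below the lowest value between replicates 1 and 3 of both lines, 0.964. With its own line the median was about as low, 0.865, so a slide effect beside the difference of replicate 2 stays open. At most 7 genes were on under 1 name and off under the other on a slide, against at least 165 between slides. The same cells under both names in replicates 1 and 3 would give this. The count restates the likeness that raised this explanation and so does not test it. Without replicate 2, MiaPaCa2 and Panc1 differed in 312 genes, Panc0403 and Panc0504 in 860, and SU8686 and Panc1005 in 562. That fit takes its spread from 2 nearly identical arrays per line (median SD 0.121), so these counts do not decide whether the cells were the same. On slide 2 the replicate 2 arrays of Panc1005 and SU8686 differed in 51 genes by the same on and off measure. That is above the 0 within slides 1 and 3 but below the 192 or more between slides in replicate 2. The count rests on single arrays, so whether the cells were the same there stays open. Which array holds which line stays open, and no array was reassigned.

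The epithelial list was lower in resistant lines, and the shift lay between slides 3 and 1. A slide effect cannot be told apart from response there, because each of those slides held a single response, and the median of 0.193 within slide 2 would follow from a slide effect or from wrong names on slide 2. The difference of SU8686 from Panc1005 correlated over genes with that of the later from the earlier array positions on slides 1 and 3 at r = 0.5 or above. A candidate explanation is therefore that the slide 2 contrast holds a difference between array positions in place of response. A real difference in response between the lines stays open and untested.

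The 10 splits of the 6 lines into 3 and 3 are too few for a share under 0.05. In the first comparison the real split gave 0 genes and the highest other split 0. Over all 9 line pairs the real split gave 2 genes, KLHDC8B and LETM2, and the highest other split 7. That split exchanged SU8686 and Panc1005, the lines of slide 2, and it also had 2775 genes at an unadjusted p under 0.05 in place of 2190. For gene lists the real split gave 12 and the highest other split 10.

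In 4 of the genes named, all arrays of SU8686 lay on 1 side of those of Panc1005 on slide 2, while slide 3 lay on the opposite side of slide 1, and the difference between these contrasts was not tested. The checkpoint ligand VTCN1 differed by 4.94 on slide 2, but its -0.634 between slides 3 and 1 lies near background, with detection on 0 of 6 and 1 of 6 arrays, and shows no direction. The interferon-induced IFI27 differed by 3.56 and was at least 37.2-fold lower on slide 3 (difference -6.39), the receptor ERBB3 by 1.32 and -4.08, and the SRC family kinase YES1 by -0.426 and 1.02.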

How the results depend on the processing

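The comparison of slides 1 and 3 alone and the counts of genes whose arrays do not overlap were chosen after the results were seen. The first comparison called 0 genes under all changes of background, scaling, detection filter or probe choice, and with trended and robust limma. Its count was 0 to 2 when a replicate number was left out and 0 to 2333 when a line was left out. It was 3 with slide as a block, 3 within slide 2, 758 with the line as a random block (within-line correlation 0.268), 2489 with the line ignored, 5417 on slides 1 and 3 only, 1 for 9 arrays against 9 apart by at least 1, and 641 for slide 3 against slide 1. Settings that enter arrays singly take the arrays of a line as replicates. On slides 1 and 3 only, the spread comes from line pairs that differed in 0 and 1 genes. Neither the genes nor the lists called there test response. Without SU8686 or Panc1005, 1 response was left with such a pair alone. For the other settings the cause was not tested. VTCN1 was at -0.634 on slides 1 and 3, a difference near background, since SU8686 carried its difference. The 2 genes over all 9 line pairs became 0 with no background correction, 1 (KLHDC8B) with an offset of 50, 0 on the authors' values, and 1333 over the 4 pairs of slides 1 and 3, and 0 to 44 when a replicate number was left out. KLHDC8B kept its call in 7 of 11 settings and LETM2 in 5.

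The 12 lists called became 5 within slide 2, 0 with an estimated correlation and 5 with fry (YAP and TEAD targets, MAPK output, receptor tyrosine kinases and ligands, neuroendocrine genes, and fibroblast markers), and were 10 to 14 with a replicate number or line left out. With slide as a block the direction turned for 11 of the 28 lists, 3 of them called in neither fit; for the other 8, adjusted p was 0.933 for basal-like PDAC, 0.00604 for classical PDAC and for the retinoid, WNT and NOTCH list, 0.168 for the epithelial and NF-kB lists, 2.13e-10 for interferon response, 0.00165 for mucins and 0.11 for NRF2. Within slide 2 it turned for 10 lists, 4 of them called in neither fit; for the other 6, adjusted p was 0.0348 for classical PDAC and for mucins, 0.25 for the epithelial list, 7.94e-08 for interferon response, 0.16 for NF-kB and 0.391 for NRF2. The cell cycle list was called lower in both (7.2e-05 and 0.000379). Of the 12 lists called, MAPK output, YAP and TEAD targets and receptor tyrosine kinases kept their call with slide as a block (0.0159, 1.58e-05 and 0.0136), and YAP and TEAD targets within slide 2 (4.95e-05). Both settings rest on SU8686 against Panc1005, 1 line each, so none of these p-values tests response.

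With a replicate number left out, the median of genes per pair of lines ran from 17 to 2844.5 for the same response and from 180 to 3431 for opposite response, and line-specific genes from 1 to 762. Line-specific genes were 16 with median centring, 16 on the authors' values and 8 under the stricter filter. Leaving out replicate 2 gave the highest of each range, as the median SD within a line then fell from 0.43 to 0.121. With a replicate block the counts were 638 for arrays with the line as a random block, 9 over the line pairs and 36 for line-specific genes. The deviations of same-numbered arrays correlated at 0.697 to 0.938 over 9 pairs from lines on 1 slide, but at -0.088 to 0.229 over 36 pairs from different slides. Differently numbered arrays correlated at -0.914 to 0.879 over 90 pairs from all lines. The highest of these lies within the range of same-numbered arrays on 1 slide. Replicate 2 stood apart in every line and lines on a slide shared its deviation, which these correlations cannot separate from pairing by number. The values within slides therefore do not show that arrays pair by number. Across slides same-numbered arrays did not deviate together, so the numbers did not pair the arrays of all lines. Genes near the detection limit have only bounds.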

Other observations

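The comparison by array position and its tests were chosen after the correlations between arrays had been seen. Genes named in it, apart from TYMS, were chosen after their values were seen. The array codes put Panc0403, Panc1005 and MiaPaCa2 at the earlier and Panc0504, SU8686 and Panc1 at the later positions of their slides, and the labels tie no condition to position.

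Cell cycle genes were lower at the later positions of every slide. All 31 measured members of the list were lower on 3 of 3 slides, with medians of -0.867, -0.776 and -0.742 on slides 1, 2 and 3 (camera adjusted p = 3.78e-19; adjusted p = 0.544 with an estimated correlation). The ribonucleotide reductase subunit RRM2 differed by -2.97, -0.78 and -0.47, and thymidylate synthase (TYMS) by -2.36, -0.78 and -0.53, although TYMS was at 0.02 on replicate 2 of slide 3. The balance between replicates varied: the list median was -1.11 in replicates 1 and 3 and -0.381 in replicate 2 on slide 1, -0.461 and -1.69 on slide 2, and -0.988 and -0.213 on slide 3. Interferon response genes moved the other way, with 23 of 31 higher on all 3 slides and medians of 0.449, 0.997 and 0.347 (adjusted p = 5.95e-10; adjusted p = 0.667 with an estimated correlation). The death ligand TNFSF10 differed by 2.02, 4.38 and 1.44, and the interferon-induced GTPase GBP2 by 1.66, 3.97 and 1.0. Cholesterol synthesis genes were lower (13 of 16 on all 3 slides, adjusted p = 0.00182), and classical PDAC genes and mucins were called higher (adjusted p = 0.00284 and 0.00266), each with adjusted p = 0.667 with an estimated correlation. Only 9 of 26 classical PDAC genes and 7 of 16 mucin genes were higher on all 3 slides, and on slide 3 their medians were 0.00119 and 0.0321.

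The difference of later from earlier positions correlated across genes at r = 0.505 between slides 1 and 2, 0.437 between slides 1 and 3 and 0.5 between slides 2 and 3. With replicate 2 kept apart from replicates 1 and 3, the 3 slides gave 6 sets of arrays, and 1176 genes were higher and 1225 lower in all 6. Independent slides give 733 in all once the sets of a slide are taken to go together as often as they did, and this count is not a test, since genes move together. Genes such as TLE2 (mean 1.21 ± 0.30, SD, n = 3 slides), IDUA (1.33 ± 0.39) and PTGES (1.81 ± 0.59) were higher, and the nuclear import factor KPNA2 (-0.99 ± 0.22), POLR3G (-0.98 ± 0.18) and CHAC2 (-0.80 ± 0.16) lower. Limma over the 3 slides called 0 genes (lowest adjusted p = 0.0712), with 2819 at an unadjusted p under 0.05 and 160 at most in the other orientations. The 4 orientations of the 3 pairs are too few for a share under 0.05, and the real one gave 0 genes and the highest other 0. As the positions also carry the labelled lines, position and line cannot be told apart.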
